A study of Apis mellifera with 4 samples.

How the data were processed

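Gene expression in the antennae of honey bee drones (males) and workers (females) was measured on 4 two-colour oligonucleotide arrays. Per the labels, each array compared 1 drone pool with 1 worker pool, each pool held 50 sets of whole antennae from bees caught at the hive entrance, and 20 µg of total RNA per pool was copied to amino-allyl cDNA and coupled to a dye. Per the design text, every pool was an independent collection, so the 4 arrays were treated as 4 biological replicates of 1 comparison. The array carried 313 genes of chosen classes, each as a long oligonucleotide printed in 2 spots, and 8 kinds of negative control oligonucleotide. The number of arrays limits the precision of every value.

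The 4 scanner files hold spot intensities that the authors deposited without normalization. Per the file headers, these are the foreground median and mean and the local background median at 635 nm (Cy5) and 532 nm (Cy3), on a scale that ends at 65535. The deposited files also give a percent of saturated pixels per spot, which was not used in any fit, and a quality score per spot with the code -75 for an absent spot and -50 for a spot that was not found. The scanner, its settings and the image software were not given in the sources used here. A further table that the authors deposited holds 1 log2 ratio per spot and array, with no statement of scale, centring or direction. Set against the scanner values, its columns ran as worker over drone on a log2 scale on all 4 arrays, with correlations across genes, after turning, of 0.98, 0.91, 0.94 and 0.98 on arrays 1 to 4. The medians of its columns were -0.02, -0.09, -0.06 and 0.08, and the method of its normalization stays unknown. That table served only as an alternative.

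The dye of each channel was taken from the label fields, which put drone in Cy3 on arrays 1 and 3 and in Cy5 on arrays 2 and 4, the even dye swap that the design text states. The free text of the labelling protocols names the other dye for arrays 2, 3 and 4 and would give 1 array with drone in Cy5. The correlations between arrays were used to check the choice, and they are given with the results.

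All values were computed with limma 3.58.1 in R 4.3.3. Foreground medians were corrected for local background with normexp and an offset of 50. Log ratios were normalized by loess within each array, with control spots at weight 0 and absent spots left out, and the spots of a gene were averaged. Ratios were turned to drone over worker and fitted as a mean of 4 arrays with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over 313 genes. A gene was called at an adjusted p under 0.05. A fold is the antilog of the mean log2 ratio, and ± is limma's standard error over 4 arrays. Loess assumes that drone over worker ratios centre on 0 at each brightness, so a shift shared by most genes of the array cannot be seen. A saturated spot kept its value. A gene left with too few arrays for a spread under an alternative was not tested there.

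Detection was counted where a gene's mean signal above local background exceeded the mean plus 2 SD of the negative control spots of that channel on at least 3 of 4 arrays. Because 1 control, oligo 4, was bright on every array, a threshold without it was added after seeing the data. That second threshold decides where a fold is only a bound. It also underlies every statement on which arrays a single gene was above the negative controls, which thus leaves out oligo 4. A gene not above it on any array of a sex is given as "at least N-fold": the mean level of the brighter sex, after loess and quantile normalization of the average intensities, against the mean of, per array, the higher of the gene's own level and the lowest level above the threshold. Where this was under 1, no fold is given. No gene's level is set against another gene's.

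Gene lists were the classes named in the design text and, within the larger classes, odorant receptors numbered up to 61 and above 61, the P450 families CYP4 and CYP6, and all other P450s. No gene of the array carried a CYP9 name, so no such list was formed, and P450 families were read from names alone. Classes were read from gene names. The 6 genes named AmCg were taken as the chemosensory proteins because that class has 6 members and no other class was left for them. The opsins served as markers of tissue other than antenna. Lists of at least 3 genes, 19 in all, were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. An exact two-sided sign-flip permutation test over 4 arrays was computed for each list and cannot give a p under 1 in 8, so it cannot reach 0.05.

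The rule for named genes, the lists, the tests and most alternatives were fixed before the data were examined. The rule took the 8 largest folds in each direction among called genes of one direction on all 4 arrays, the gene with the smallest adjusted p in each class, the 4 housekeeping genes, Or2, the sensory neuron membrane protein, Or10, Or11, Or18 and Or170, and the long-wavelength opsins. Those 4 receptors are known from a published study made on these same samples, so their direction here is not independent evidence. Other genes are named only where said to have been chosen after their values were seen.

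Gene names are those of the array's design, which was made on Assembly 2 of the bee genome per the design text. Of 313 names, 67 were found in the RefSeq gene table of assembly Amel_HAv3.1, 35 of them odorant receptors. That table was used only for names and neighbours, and no coordinates are given because the builds differ.

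On data simulated from the spread of the real arrays (20 simulations, 60 of 313 genes changed), the procedure recovered 24% of changes of 0.6, 87% of changes of 1.5 and 99% of changes of 3 on the log2 scale. Of its calls, 4% were false and 0 had the wrong direction, and simulations without changes gave 0 calls. A shift of -1 of the odorant binding proteins was recovered in 20 of 20 simulations, against an observed median of -0.28 and mean of -0.83. The simulated noise was independent between genes and arrays, without dye effects specific to genes, print block effects or correlation between genes. These rates therefore need not hold for the real arrays.

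Alternatives covered the background correction, the normalization, foreground means, spot flags, a filter on dim genes, a dye coefficient, the averaging of both arrays of slide 7, the variance model, unpaired channels, the authors' deposited ratios, the protocol-text dyes and each array left out. Added after seeing the data were the removal of saturated spots, the detection threshold without oligo 4, a dye coefficient without array 4 and the removal of print block medians. The alternatives by centring and the one without normalization left out loess. Slide 7 carried arrays 3 and 4, of opposite dye orientation, and every array holds both sexes. A correlation within slides could not be estimated with only 1 slide holding more than 1 array.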

Results

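The series asked which chemosensory and related genes differ in expression between drone and worker honey bee antennae. Antennae of both sexes carry olfactory sensilla, and the array was built around the odorant receptor family. On 4 arrays, each with a drone pool against an independent worker pool, 313 genes were measured, of which 168 were odorant receptors. The median signal above background ran from 42 in Cy5 and 105.5 in Cy3 on array 2 to 611 in Cy5 on array 3 and 643 in Cy3 on array 4. The SD of a single spot's log2 ratio within a gene, taken from the duplicate spots, was 0.18 to 0.22.

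In all, 37 genes differed between the sexes at an adjusted p under 0.05 (limma, n = 4 arrays). Of these, 14 were higher in drone and 23 higher in worker antennae, and each of the 37 had the same direction on 4 of 4 arrays. At an unadjusted p under 0.05 there were 68 genes. The called genes spanned receptors, binding proteins and enzymes, with the largest fold of each direction in an enzyme gene.

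The gene with the largest fold in drones was AmCEst01, a carboxylesterase, a class of enzymes that cleave esters. It was 27.4-fold higher in drone antennae (log2 4.77 ± 0.40, adjusted p = 4.99e-04), with the drone channel saturated on 3 of 4 arrays, so the fold is likely understated. On array 2, the only one without saturation, its log2 ratio was 5.91. AmOr011, known as a receptor for the main component of queen pheromone, was 10.9-fold higher (log2 3.45 ± 0.17, adjusted p = 4.07e-05). AmOr018 was 4.01-fold higher (log2 2.00 ± 0.36, adjusted p = 0.0135). Its worker signal was above the negative controls on 2 of 4 arrays, by the threshold without oligo 4 that is used for every single gene. AmOr170 was 3.17-fold higher (log2 1.67 ± 0.36, adjusted p = 0.0303), above the controls on 3 arrays in drone and 1 in worker. AmOr010 was not above the negative controls in worker on any array and was at least 1.79-fold higher in drone (adjusted p = 9.79e-04). Among the non-receptor genes, the lipocalin AmLip1, of a family that carries small hydrophobic molecules, was 2.99-fold higher (log2 1.58 ± 0.16). The glutathione S-transferase AmGST1 was 2.65-fold higher (log2 1.40 ± 0.26), with the drone channel saturated on 1 array, and the cytochrome P450 AmCyp305D1 at least 1.28-fold higher, since its signal was above the controls on 2 arrays in drone and on none in worker.

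With the dyes of the protocol texts 0 drone and 0 worker genes were called. With the label-field dyes, AmOr011 passed the threshold under all 22 other settings, and AmCEst01 under the 21 that left it more than 1 array. AmOr010 missed it under housekeeping centring and without normalization, with adjusted p up to 0.731, and AmLip1 under median and housekeeping centring, with adjusted p up to 0.161. AmOr018 missed it without array 1, 2 or 3, with adjusted p of 0.0857, 0.0956 and 0.0621, and AmOr170 did so with 0.162, 0.155 and 0.149. Over the settings with the label-field dyes the adjusted p ran from 2.59e-05 to 0.341 for AmOr018 and from 4.89e-05 to 0.998 for AmOr170. AmGST1 missed the threshold without array 1 (0.0857) or 2 (0.0989), in a range from 3.41e-04 to 0.181. AmCyp305D1 missed it without array 2 (0.0599), in a range from 4.89e-05 to 0.731. AmOr170 and AmGST1 also missed it under median, housekeeping and non-receptor centring and without normalization, and AmGST1 with a dye coefficient without array 4. AmCyp305D1 also missed it under median and housekeeping centring and without normalization, and AmOr018 under housekeeping centring. The drone count of 14 was 7, 6 and 8 without arrays 1, 2 and 3. Leaving out an array also makes the dye swap uneven, so fewer arrays and dye effects cannot be told apart in these losses.

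**Figure D1:**
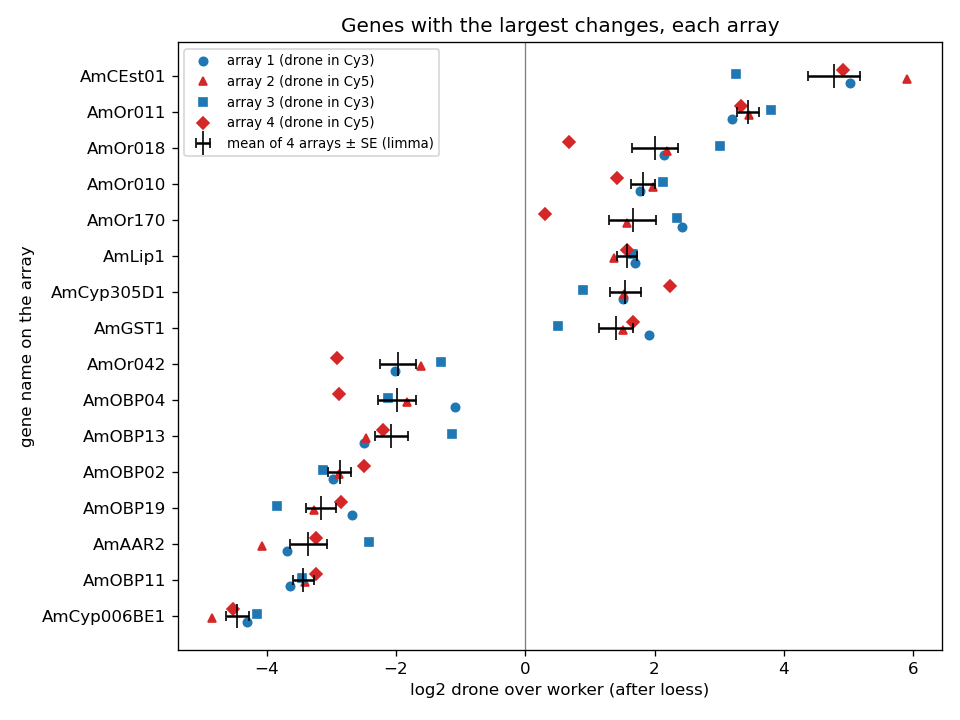
Log2 drone over worker ratio after loess (x axis) of the 8 genes with the largest folds in each direction (y axis), with 1 symbol per array, colour for the dye of the drone sample, and black crosses for the mean of 4 arrays ± limma's standard error. AmOr018 and AmOr170 lie at 0.68 and 0.31 on array 4, below their other arrays, and the ratios of AmOr010 and AmCyp305D1 are fitted values of genes whose worker signal was not above the negative controls.

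In worker antennae the largest fold belonged to a cytochrome P450, AmCyp006BE1, of the CYP6 family that includes many enzymes acting on plant and other foreign compounds. It was 21.9-fold higher in worker (log2 -4.45 ± 0.18, adjusted p = 3.08e-05). Odorant binding proteins, soluble carriers of odorants in the fluid around olfactory neurons, made up 5 of the 8 largest worker folds. AmOBP11 was 10.8-fold higher (log2 -3.43 ± 0.16, adjusted p = 3.63e-05), with drone signal above the controls on 2 of 4 arrays. AmOBP19 was 8.94-fold higher (log2 -3.16 ± 0.23), AmOBP02 7.31-fold (log2 -2.87 ± 0.17), and AmOBP13 4.20-fold (log2 -2.07 ± 0.26, with the worker channel saturated on 1 array). AmOBP04 was 3.94-fold higher (log2 -1.98 ± 0.29), with the worker channel saturated on 3 arrays, so the fold is likely understated. On array 4, the only one without saturation, its log2 ratio was -2.88. AmAAR2, an alpha-arrestin, was 10.2-fold higher (log2 -3.36 ± 0.28, adjusted p = 4.99e-04). The odorant receptor AmOr042 was 3.90-fold higher (log2 -1.96 ± 0.28, adjusted p = 0.00468).

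Smaller worker folds were seen in the best-ranked members of other classes. AmCg5, taken as a chemosensory protein, was 3.08-fold higher in worker (log2 -1.62 ± 0.16), the tetraspanin AmTspan12 2.86-fold (log2 -1.52 ± 0.19) and the glutathione S-transferase AmGST7 2.63-fold (log2 -1.39 ± 0.15). AmCyp006BE1 and AmOBP11 passed under all 22 settings with the label-field dyes. The other worker genes named so far missed the threshold under median centring. AmOBP13, AmOBP04, AmOr042, AmCg5, AmTspan12 and AmGST7 also missed it under housekeeping centring. AmGST7 missed it too under non-receptor centring, without normalization and with unpaired channels, with adjusted p up to 0.524. Without array 2 the worker count of 23 was 13, the lowest count when 1 array was left out.

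The split of 14 drone and 23 worker calls differed with the normalization. Loess was left out in each setting that follows, so the counts do not separate the centring from the lack of loess. Centring each array on the median of its genes gave 4 and 4 calls, centring on the housekeeping genes 2 and 5, centring on the genes that are not odorant receptors 6 and 15, and no normalization 4 and 13. Housekeeping centring put the median of all genes at -0.25 and no normalization put it at -0.10. Under none of these did a gene of the 37 change sign.

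Whether the receptor family as a whole leans to one sex was examined by class. Of 168 odorant receptors, 6 were higher in drone and 8 higher in worker, and 154 were not called. The counts adjusted over the list alone were the same, 6 and 8. The median receptor had a log2 ratio of -0.02, and no shift of the family against the other genes was detected (camera adjusted p = 0.894). Receptors were 99 of the 156 dimmer genes, and loess centres the ratios at each brightness. A median near 0 is therefore largely set by the normalization and does not show that the family is balanced. Even without oligo 4, only 21 receptors were detected in drone and 25 in worker. The receptor median depends on the normalization. It was -0.36 under housekeeping centring, -0.22 without normalization, -0.19 under non-receptor centring and -0.04 under median centring, all without loess. Besides AmOr010, AmOr011, AmOr018 and AmOr170, the drone receptors were AmOr064 and AmOr078, named after their values were seen, with log2 ratios of 1.25 ± 0.17 and 1.30 ± 0.15. The worker receptors were AmOr042, AmOr063, AmOr081, AmOr099, AmOr109, AmOr149, AmOr150 and AmOr151, of which all but AmOr042 were likewise named after their values were seen. AmOr063 was at least 1.31-fold higher in worker, and AmOr099, AmOr109, AmOr149 and AmOr150 have no fold because their bound was under 1. In all 5 the drone signal was not above the controls on any array. AmOr002, the co-receptor that pairs with other odorant receptors, was not called (log2 0.42 ± 0.16, adjusted p = 0.174), and passed only when the test was limited to the 36 detected genes (0.0415, in a range up to 0.958). Without arrays 1, 2 and 3 the worker receptors called numbered 3, 1 and 3, and housekeeping centring left 0 of them, beside 1 in drone. At an unadjusted p under 0.05, 26 of the 313 genes passed under that centring.

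Among receptors numbered up to 61, 3 were higher in drone and 1 in worker, with a median log2 ratio of 0.06. Among the 107 numbered above 61, 3 were higher in drone and 7 in worker, with a median of -0.10. Neither list was shifted by camera (adjusted p = 0.230 for both), and the difference between them was not tested. Both medians depend on the normalization. Up to 61 and above 61 they were -0.27 and -0.41 under housekeeping centring, and -0.10 and -0.23 under non-receptor centring. Without normalization they were -0.13 and -0.26, and under median centring 0.05 and -0.08.

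The odorant binding proteins were the only 1 of 19 lists shifted in the camera test. Of 19 genes, 7 were higher in worker and 0 higher in drone, with 7 and 1 when adjusted over the list alone, the 1 being AmOBP07 (log2 0.58 ± 0.18), named after its value was seen. Its drone channel was saturated on 1 array, and without saturated spots its log2 ratio was 0.42 on 3 arrays, with an adjusted p over all genes of 0.342 against 0.114. AmOBP01, also named after its value was seen, leaned to drone but was not called (log2 0.82 ± 0.57, adjusted p = 0.505). It had 3.25 on array 2, and was saturated on 3 arrays in drone and 1 in worker. Without saturated spots AmOBP01 kept 1 array, at log2 -0.23, and had no test, so its direction stays open. AmOBP05 and AmOBP16, also named after their values were seen and saturated in worker on 1 and 2 arrays, were not called, but without saturated spots they passed as higher in worker (log2 -1.27 on 3 arrays, adjusted p = 0.0265, and -1.59 on 2 arrays, adjusted p = 0.0290). The list's median log2 ratio was -0.28 and its mean -0.83 (camera adjusted p = 0.00205), and the medians of the 4 arrays were -0.29, -0.29, -0.52 and -0.42. With an estimated correlation no list passed, and this list had an adjusted p = 0.735 with an estimated correlation. In the exact two-sided sign-flip permutation test over 4 arrays its p was 1 in 8, the smallest that test can give. The list also missed the threshold under median centring (0.104), where its median was -0.04, non-receptor centring (0.114) and no normalization (0.124).

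Of 49 cytochrome P450s, 4 were higher in drone and 4 in worker, also when adjusted over the list alone, and the list was not shifted (camera adjusted p = 0.808). Its median was 0.08 and its mean -0.04, and the median was -0.15 under housekeeping centring, -0.01 without normalization, 0.02 under non-receptor centring and 0.18 under median centring. CYP6 held 2 drone and 2 worker calls among 22 genes (adjusted p = 0.766), CYP4 none among 3 (0.927), and all other P450s 2 and 2 among 24 (0.927). Of 10 carboxylesterases 2 were higher in drone, also when adjusted over the list alone, AmCEst01 and AmCEst06, the latter named after its value was seen (log2 0.87 ± 0.18). The camera adjusted p of the list was 0.398. The 7 glutathione S-transferases held 1 call in each direction and 3 drone calls and 1 worker call when adjusted over the list alone, where AmGST3 and AmGST6 were added, named after their values were seen (camera adjusted p = 0.589). Among 6 chemosensory proteins 1 was higher in worker (camera adjusted p = 0.230), among 17 tetraspanins 1 in worker (0.398), among 5 lipocalins 1 in drone (0.398) and among 4 alpha-arrestins 1 in worker (0.927), where the median was 0.15 and the mean -0.62, and the median was -0.12 under housekeeping centring, 0.02 without normalization, 0.05 under non-receptor centring and 0.20 under median centring. These 4 counts were the same when adjusted over the list alone. Of the chemosensory proteins, AmCg1 and AmCg3, named after their values were seen, had saturated spots. AmCg1 was saturated on 4 of 4 arrays in worker and on 3 in drone. It had 0 arrays left without saturated spots, so its log2 ratio of -0.30 rests on saturated signal. AmCg3 was saturated on 2 arrays in worker, and its log2 ratio went from -0.65 to -1.32 on 2 arrays without saturated spots (adjusted p = 0.0915).

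No member of the 10 gustatory receptors, 5 opsins, 4 arrestins, 3 G-protein alpha subunits or 4 housekeeping genes was called by limma over all genes. Their camera adjusted p were 0.589, 0.589, 0.946, 0.398 and 0.946. AmGpAsOlf, a G-protein subunit, had a log2 ratio of 0.51 ± 0.16 (adjusted p = 0.111), and 0.0490 when adjusted over the list alone. It passed with print block medians removed (0.0400) and among the 105 genes detected without oligo 4 (0.0274), in a range up to 1.00. The best-ranked gustatory receptor, AmGr3, had 0.37 ± 0.17 (adjusted p = 0.253). Of the opsins, AmLop1 was above the negative controls on no array in drone and on 2 in worker (adjusted p = 0.976), and AmLop2 and the arrestin AmARR1 were not above them on any array in either sex. AmBLop, the best-ranked opsin, was above them on 1 array in drone and none in worker (adjusted p = 0.624). The sensory neuron membrane protein AmSNMP had -0.49 ± 0.18 (adjusted p = 0.173, and 0.0415 among the 36 detected genes, in a range up to 1.00) and AmPin, the bee Pinocchio gene, -0.02 ± 0.19. The housekeeping genes AmEF1alpha, AmRPS3 and AmRP49 had 0.05 ± 0.17, 0.04 ± 0.15 and -0.21 ± 0.16, each with another sign under at least 1 alternative. AmCytoActin had 0.01 ± 0.33, with 1.28 on array 4 and -0.52 to -0.23 on the others.

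**Figure D2:**
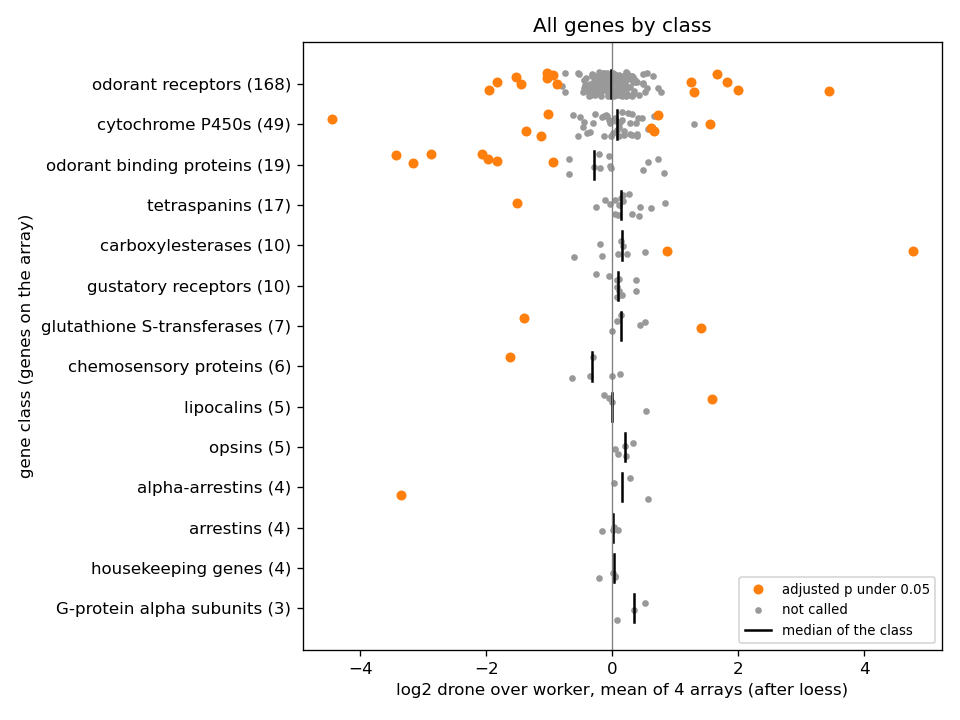
Log2 drone over worker ratio, mean of 4 arrays after loess (x axis), of each gene by class (y axis, number of genes in brackets), with orange points for adjusted p under 0.05, grey points for genes not called and black bars for class medians. The 7 called odorant binding proteins lie on the worker side, while the 14 called odorant receptors lie on both sides.

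Detection against the negative controls was low by the rule fixed beforehand. In drone antennae 28 of 313 genes and in worker antennae 26 were above the controls, among them 3 and 0 odorant receptors. Of the odorant binding proteins, 9 were detected in drone and 12 in worker. With oligo 4 left out of the threshold, a choice made after seeing the data, 90 genes were detected in drone and 97 in worker, with 21 and 25 receptors. A receptor not above this threshold was not detectable here, which does not show that it is absent.

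Array agreement was measured across genes, which are not independent replicates. Turned by the label fields, the 6 pairs of arrays correlated at r = 0.78 (1 and 2), 0.76 (1 and 3), 0.42 (1 and 4), 0.69 (2 and 3), 0.73 (2 and 4) and 0.39 (3 and 4), with Spearman's rho of 0.45, 0.62, 0.05, 0.40, 0.63 and 0.04. Turned by the protocol text instead, the lowest r was -0.775. Arrays 3 and 4 shared slide 7 and had the lowest r. Among the brighter 157 genes r ran from 0.61 to 0.87, and among the dimmer 156 from -0.36 to 0.50. Of the 37 called genes, 33 were in the brighter part.

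**Figure D3:**
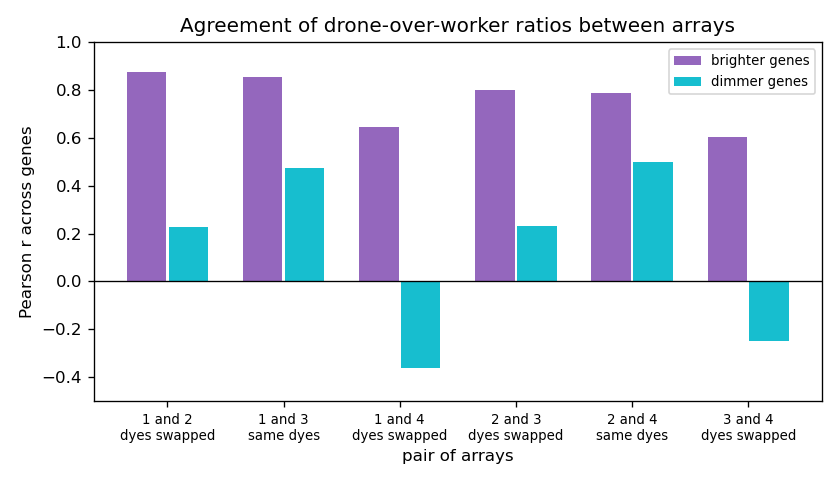
Pearson correlation across genes (y axis) of the drone over worker log2 ratios of each pair of arrays (x axis), for the 157 brighter (purple) and 156 dimmer (cyan) genes. In the dimmer genes array 4 correlated at -0.36 with array 1 and -0.25 with array 3, the arrays of the opposite dye orientation. Array 2, of the same orientation as array 4, correlated with arrays 1 and 3 at 0.227 and 0.230 in these genes.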

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

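The tests on array 4 were chosen after its correlations had been seen, and the removal of print block medians was an alternative added then. Among 51 sets of 4 array values, 1 stood apart, where chance alone marks about 1 in 20. It was the housekeeping gene AmCytoActin, whose log2 ratio was 1.28 on array 4 against -0.52 to -0.23 on the other arrays, a gap of 0.836 of the whole range, just above the critical value of Dixon's test.

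Negative control oligo 4 gave signal in spots meant to stay dark. It was 14.3-fold brighter than the next brightest of the 8 negative controls in the drone channel, with mean signals above background of 6897 and 482. In the worker channel it was 10.5-fold brighter, with 6658 and 636. These are ratios of means over arrays of different brightness, and array by array the fold over the next brightest control ran from 8.54 to 28.2 in drone and from 5.58 to 25.3 in worker.

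Array 4 departed from arrays 1 and 3 in the whole set of genes, with r of 0.42 and 0.39, and 3 technical explanations were weighed; a difference between the bee pools stays open and was not tested. Weaker ratios of dim genes alone would lower the slope of array 4 toward 0. The slope was lower in dim than in bright genes by 1.12 (95% bootstrap interval 0.718 to 1.54), and the interval of the slope in dim genes, -0.28 (-0.69 to 0.09), held 0. Yet in dim genes array 4 ran against the mean of arrays 1 and 3 at r = -0.354 (-0.536 to -0.151) and with array 2 at 0.500 (0.351 to 0.633). Compression alone cannot make r negative, so it is not the cause by itself. In bright genes the lower r was 0.606 (0.399 to 0.746), which leaves open whether dim genes are the whole of it. Print blocks explained 19.3% of the departure against 4.81% in shuffles (permutation p = 0.0001, the smallest that 10000 shuffles can give), yet removing block means raised the lower r only to 0.451 (0.266 to 0.582), so uneven blocks are not the whole cause, and array 1 showed more of it (25.5%). A dye effect specific to each gene remains a candidate explanation. Array 4 minus array 3 correlated with array 2 minus array 1 at r = 0.532 (0.434 to 0.625) without sharing an array. Yet array 2, of the same dye orientation as array 4, correlated with arrays 1 and 3 at r = 0.78 and 0.69. In dim genes these values were 0.227 and 0.230. A dye effect equally strong on arrays 2 and 4 therefore leaves the lower r of array 4 unexplained. One that is stronger on array 4 was not tested. Before normalization the median log2 ratio of Cy5 over Cy3 was -0.64, -0.30, -0.08 and -1.15 on arrays 1 to 4. A dye effect specific to each gene cancels in the mean of an even dye swap where it is equally strong on each array. With a dye coefficient in the model 1 gene passed for the dye itself, which was not among the 37, and 56 had an unadjusted p under 0.05. That fit called 20 drone and 30 worker genes, with 8 and 12 receptors, against 14 and 23, with 6 and 8.

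Chance could be weighed only against 8 sign patterns of the 4 arrays, too few for a share under 0.05. The real pattern called 37 genes and the highest other pattern 0, so that 1 of 8 patterns gave as many. For odorant receptors the values were 14 and 0 (1 of 8), and for gene lists 1 and 0 (1 of 8). At an unadjusted p under 0.05 limma gave 68 genes for the real pattern and up to 34 for the others, the 34 from the pattern that follows the dyes. For receptors these counts were 24 and up to 17, and for lists in the camera test 4 and up to 4.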

How the results depend on the processing

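Tests with saturated spots left out, detection without oligo 4, a dye coefficient without array 4 and print block medians removed were chosen after the results had been seen. None of the 37 called genes changed sign under any of the 22 settings with the label-field dyes in which it was tested; 16 and 31 of them were tested when limited to genes detected with and without oligo 4, and 35 with saturated spots left out, where AmCEst01 and AmOBP04 kept 1 array and had no test. Of 408 values of the 19 called named genes, 364 stayed past the threshold and 44 did not, and 4 values of genes not called passed it. Against 14 drone and 23 worker genes, with 6 and 8 receptors, median centring gave 4 and 4 (receptors 3 and 2), housekeeping centring 2 and 5 (1 and 0), non-receptor centring 6 and 15 (3 and 6) and no normalization 4 and 13 (2 and 4). None of these settings used loess, so the choice of centring and the lack of loess cannot be told apart, and the cause was not tested. Unpaired channels gave 8 drone genes, where the array no longer pairs the samples. Only 36 genes were tested when limited to those detected, with 13 worker genes and 3 and 0 receptors, and 105 without oligo 4, with 5 worker receptors. With 1 array left out, drone genes numbered 6 to 14, worker genes 13 to 29, drone receptors 4 to 8, worker receptors 1 to 12 and lists 1 to 1. These fits had an uneven dye swap and no dye coefficient, so dye effects specific to a gene did not cancel in them. Lists past the threshold, 1 in the camera test, were 0 with an estimated correlation, 0 under median centring, 0 under non-receptor centring and 0 without normalization. By fry, which asks whether a list shifts at all and not against the other genes, 4 lists passed. The chemosensory proteins (fry adjusted p = 0.00615) and odorant binding proteins (0.0209) leaned to worker. The G-protein alpha subunits (0.0249) and the receptors up to 61 (0.0373) leaned to drone. Detected genes rose from 28 to 90 in drone and from 26 to 97 in worker without oligo 4. The lowest correlation between arrays turned to -0.775 with the dyes of the protocol text, which gave 0 drone and 0 worker genes. The authors' deposited ratios called 36 genes, 35 of them shared. A slide block was not run, since its correlation could not be estimated. Of the 37 genes, 4 were among the 156 dimmer.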

Other observations

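The tests in this part were chosen after the values had been seen, and so were its genes apart from AmOr010 and AmOr011. Within the cytochrome P450s, calls of related enzymes ran both ways. AmCyp335B1 and AmCyp335B3 were higher in worker, at log2 -1.13 ± 0.15 and -1.37 ± 0.23. In the CYP6AS group, AmCyp006AS04 and AmCyp006AS05 were higher in drone by 0.73 ± 0.15 and 0.61 ± 0.15, and AmCyp006AS14 was higher in worker, at -1.02 ± 0.24. AmCyp302A1, of the family that acts in ecdysteroid synthesis, was higher in drone by 0.66 ± 0.15, with signal above the negative controls on 2 of 4 arrays in each sex. All 6 had one direction on 4 of 4 arrays. Further odorant binding proteins higher in worker were AmOBP14 (-1.84 ± 0.25) and AmOBP15 (-0.94 ± 0.22).

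AmOr010 and AmOr011, both higher in drone, are neighbours with 0 genes listed between them in the RefSeq table, while AmOr009 had 0.56 ± 0.29 and AmOr012 0.00 ± 0.16, neither called. Over the receptors numbered up to 61, consecutive receptors differed by 0.440 on average against 0.547 in shuffled orders (permutation p = 0.0024, 10000 shuffles), and still by less than chance without these 2 (permutation p = 0.0161). After removal of print block medians the permutation p was 0.0688, but 0% of consecutive receptors share a print block, so a shared block is not the cause. Cross-hybridization between similar neighbours may contribute, and so may shared regulation of neighbours. Probe sequences were not used here, and nothing measured separates these explanations from each other or from the print layout.

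AmOr149, AmOr150 and AmOr151 were all higher in worker, with AmOr151 at -1.83 ± 0.30 on the log2 scale. No likeness of consecutively numbered receptors above 61 was detected once these 3 were left out, where consecutive receptors differed by 0.433 against 0.453 in shuffles (permutation p = 0.1931). Whether the 3 genes are neighbours was not analysed here.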
